A study of Mus with 8 samples.

How the data were processed

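Liver RNA of 8 samples, each on its own expression array, was compared: 4 samples labelled Control and 4 labelled LKB1 KO, all collected 48 h after partial hepatectomy. Per the labels' protocols, total RNA was isolated with TRIzol, reverse transcribed and amplified to sense-strand cDNA with the Ovation PicoSL kit (single primer isothermal amplification), then fragmented and labelled with biotin using the Encore module. The deposited table holds 1 log2 expression value per row and array, already summarised and normalized by the authors. The submitters' processing notes name RMA (robust multi-array average, which subtracts background, normalizes arrays to a common distribution and summarises the probes of a gene) and the Partek software, without versions. The array design, the probe annotation and the genome build are not given in the sources used here, so no coordinates are printed, and it is not known which exons the probes of a gene cover. As deposited, the medians of the arrays over the named genes ran from 3.75 to 3.96 log2 units. RMA compresses differences between dim probes, so folds of weakly expressed genes are uncertain, and probes of related genes can pick up each other's transcripts.

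Of 25206 rows, 23185 had 1 gene symbol in the platform annotation, 0 had several and 2021 had none, and no symbol had more than 1 row. The comparison was made over the 23185 named rows, without a filter on level. All 8 columns of values were matched to a sample by name, and no value was missing. Groups were taken from the sample titles. The titles carry replicate numbers from 1 to 4 in both groups but do not say that equal numbers share an animal, litter or day, so the model had the group as its single term.

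A linear model was fitted to each gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over the 23185 genes, with a threshold of 0.05 in either direction. Differences are LKB1 KO minus Control in log2 units with their moderated standard errors (SE), and n is 4 arrays per group. The p-values measure the spread between these samples, which the labels do not describe as separate animals and which may in part be technical. For arrays, the number of samples limits the precision. Across 4 against 4 arrays an exact two-sided permutation test cannot give a p below 0.0286.

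A set of 40 gene lists was fixed before the data were examined. They cover the LKB1 and AMPK-related kinases, the cell cycle, metabolism, liver zonation, stress and hormone responses, sex-biased genes and markers of the cell types that a liver sample can hold. Of the 797 measured genes on them, 37 stand on more than 1 list. Each list is described by its members past the threshold over all genes, by the count adjusted over the list alone, and by its median difference. It was tested with limma's camera at the preset inter-gene correlation of 0.01, two-sided, adjusted over the 40 lists. Camera asks whether a list moved relative to all other genes. Beside it stand camera with a correlation estimated for each list, fry (which asks whether the members move, on balance, one way) and an exact permutation test of the list's median deviation per array.

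The rule for named genes was also fixed beforehand. It names Stk11, the 12 largest rises and 12 largest falls past the threshold among genes whose arrays did not overlap between the groups (placeholder symbols left out), and up to 5 members of each list past the threshold, with at least 1 from the rarer direction. Where fewer than 2 members passed, the 2 with the smallest p are given as values. The alternatives planned beforehand were the replicate number as a block, each array left out in turn, quantile normalization, centring of each array on its median, removal of the dimmest genes (the lowest of 3 equal bins by mean level), a trended and robust prior variance, no moderation of variances, array weights, all 25206 rows, a fold of at least 1.5, an adjusted p under 0.01, the 2 other list tests, and removal of dim list members. A fit without both LKB1 KO 2 and Control 4 was added after the arrays had been seen. The mean over several rows of a gene, also planned, could not differ from the values used, since each gene had 1 row.

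The fit was tested on simulated data for this comparison, with 200 of the 23185 genes changed in each of 20 runs. It recovered 8.13% of the genes changed by 0.5 log2 units, 64.0% of those changed by 1 and 96.3% of those changed by 2, and 4.85% of its calls were unchanged genes. Those simulated genes varied independently, so the 1 call among 800 unshifted list tests says nothing of lists whose members vary together. Each simulated gene also had the same normal spread in both groups, and no simulated array stood apart. The rates for single genes therefore hold for such simpler data and may differ for the real arrays. As a gauge of background, chosen after the results had been seen, the mean levels of 1350 olfactory and vomeronasal receptor genes were taken, with a median of 2.11 and a 95th percentile of 3.73 log2 units. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.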

Results

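Expression arrays were run on mouse liver taken 48 h after partial hepatectomy, an operation in which part of the liver is removed and the remainder grows back. The design sets livers labelled Control against livers labelled LKB1 KO and asks how their transcripts differ at that time. LKB1, the product of Stk11, is a protein kinase that activates AMPK and the related kinases of the SIK, MARK and NUAK families. Each group held 4 arrays, and each array gave a log2 value for 23185 named genes. The median value per array lay between 3.75 and 3.96 log2 units, and the correlation between arrays lay between 0.960 and 0.988. The number of arrays limits the precision of each value. LKB1 KO 2 stood farthest from the rest, with the highest median, the narrowest spread of values (SD 1.92 over genes, against up to 2.10) and a mean correlation of 0.974 with its own group. Control 4 had the lowest mean correlation among the Control arrays, 0.976. The first principal component held 30.6% of the variance and separated the groups.

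Stk11 (Entrez Gene 20869) was lower in all 4 LKB1 KO arrays. Its log2 values were 6.69, 6.68, 6.46 and 6.76 in Control 1 to 4 and 3.98, 3.97, 4.84 and 4.22 in LKB1 KO 1 to 4, with means of 6.64 ± 0.13 and 4.25 ± 0.41 (SD, n = 4). The difference of -2.39 (SE 0.19, 95% confidence interval -2.82 to -1.97) corresponds to a 5.25-fold lower level, with a limma adjusted p of 0.000453. No array went against its label. All 4 LKB1 KO values stayed above the background gauge of 3.73 log2 units. Those of LKB1 KO 1 and LKB1 KO 2 lay close to it and to the medians of their arrays (3.86 and 3.96). The size of the fall is therefore uncertain. The position of the probes relative to the deleted part of the gene is not known. Among the 24 measured genes of the LKB1 complex and the AMPK-related kinases, Stk11 fell and Sik1 rose, also when adjusted over the list alone, and 22 did not pass the test. The median of that list was 0.03 log2 units (camera adjusted p = 0.712).

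Among the genes past the threshold, more were lower than higher in the LKB1 KO livers. This did not hold over all 23185 genes tested, of which 12261 had a difference above 0, with a median of 0.016 log2 units. In all, 458 genes passed the threshold, of which 113 were higher and 345 lower in LKB1 KO, and 69 and 159 of these differed at least 2-fold. The largest mean difference was in the leptin receptor gene Lepr (3.81, SE 0.53, adjusted p = 0.00542), whose Control arrays ranged from 2.60 to 5.15. The nuclear receptor gene Nr4a1 rose 12.5-fold (3.64, SE 0.19, adjusted p = 1.41e-05) and Kiss1, which encodes the peptide hormone kisspeptin, rose by 3.24 log2 units (SE 0.36, adjusted p = 0.00182). Htra1, a secreted serine protease gene, rose 7.61-fold, and the steroid hydroxylase gene Cyp17a1 rose 7.09-fold. Fst, the gene of the activin antagonist follistatin, rose 5.72-fold, and Sik1, a kinase of the LKB1-dependent family, rose 5.14-fold. The remaining rises among the 12 largest were in Gtdc1 (5.08-fold), the prolyl hydroxylase gene Egln3 (5.02-fold), the TWEAK receptor gene Tnfrsf12a (4.71-fold), the transcription factor gene Egr1 (4.65-fold) and Prom1 (4.61-fold). With single arrays left out the differences of Lepr (3.41 to 4.25) and Nr4a1 (3.46 to 3.74) overlapped, so their order is not fixed. Kiss1 lay below the background gauge of 3.73 log2 units in all 4 Control arrays, Lepr and Prom1 in 2 and Htra1 in 1, so the sizes of these rises are uncertain. Among the 12, adjusted p lay between 1.41e-05 for Nr4a1 and 0.0239 for Egr1.

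The largest falls were in Elovl3, a fatty acid elongase gene, at 12.9-fold lower (difference -3.69, SE 0.59, adjusted p = 0.0110), and in the carboxylesterase gene Ces3b, at 12.2-fold lower (-3.60, SE 0.40, adjusted p = 0.00181). Csrp3 stood at a difference of -3.45 (SE 0.26), and the galactosyltransferase gene B3galt1 was 10.4-fold lower. All 4 LKB1 KO arrays of Csrp3 lay below the background gauge, as did 2 of Fabp5 and 1 each of Elovl3, Ces3b, Cyp4a12a and Serpina4-ps1, so the sizes and order of these falls are uncertain. Saa4, a serum amyloid A gene, was 8.19-fold lower (-3.03, SE 0.13, adjusted p = 3.08e-06), the smallest adjusted p of all genes. Cyp4a12a, a fatty acid hydroxylase gene, was 8.05-fold lower, the fatty acid binding protein gene Fabp5 6.95-fold, Selenbp2 6.55-fold and Keg1 6.06-fold. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, was 5.39-fold lower, and Stk11 completes the 12. The pseudogene Serpina4-ps1 was 9.42-fold lower, but its probes may share sequence with related serpin genes and its value is uncertain, as are those of Cyp4a12a and Ces3b within their gene families.

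In each of the 458 genes the arrays of the groups did not overlap. A call with 4 arrays per group leaves little room for overlap, so this is no separate support for the calls. Over all genes, 2049 (8.84%) had arrays that did not overlap, where chance gives 2.86%. Placeholder symbols made up 34 of the 458. The count fell to 242, 213, 232, 235 and 234 when Control 1, Control 2, LKB1 KO 1, LKB1 KO 3 or LKB1 KO 4 was left out, and quantile normalization gave 198 genes higher and 340 lower (36.8% higher, against 24.7% as deposited). Without LKB1 KO 2, 363 genes passed, 229 of them lower. Among the largest changes, single arrays left out ended the calls of Tnfrsf12a (Control 2, LKB1 KO 3 or LKB1 KO 4, adjusted p up to 0.0525), Egr1 (Control 1, LKB1 KO 1, LKB1 KO 3 or LKB1 KO 4, up to 0.0815), Serpina4-ps1 (any array but Control 3, up to 0.0993) and Cyp7a1 (any array but Control 4, up to 0.0998). Without moderation of variances 97 genes passed, and 66 of the named genes lost their calls. Among the largest changes these were Lepr, Kiss1, Cyp17a1, Egln3, Tnfrsf12a, Egr1 and Prom1, and Elovl3, Ces3b, B3galt1, Serpina4-ps1, Cyp4a12a, Selenbp2, Keg1 and Cyp7a1 (adjusted p from 0.0532 for B3galt1 to 0.228 for Serpina4-ps1). Of the list members named further on, those that kept their calls in that fit were Atf3, C6, Clec4g, Cyp2e1, Dgat2, Egfr, Erbb3, Fas, Gpr182, Ido2, Nr1i3 and Pigr, beside genes already given. Without both LKB1 KO 2 and Control 4, 24 named genes lost their calls, among them G6pc (0.0520), Slc37a4 (0.0549) and Acot2 (0.0520), which had kept them with single arrays left out. A trended and robust prior ended the calls of Serpina4-ps1 and, among the list members named further on, Igfbp1 (adjusted p = 0.0729 and 0.0691). Median centring ended those of Plk1, Mad2l1, Gtse1, Fbp1, Plin2, Slc51b, Lhpp and Kdr (0.0503 for Kdr to 0.105 for Fbp1), and quantile normalization those of Hsd17b6, Csf1r, Kdr and Alas2 (0.0516 for Kdr to 0.0796 for Alas2).

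Some named genes that did not pass were called under other settings. With array weights Ccnd1 (adjusted p = 0.0412), Cep55 (0.0239), Ect2 (0.0346), Cxcl10 (0.0416), Srxn1 (0.0190), Birc5 (0.0238), Gadd45b (0.0119), Per1 (0.0400) and Rgs5 (0.0470) passed. Quantile normalization gave calls to Ccnd1 (0.0497), Birc5 (0.0314) and Per1 (0.0496), the trended and robust prior to Birc5 (0.0413) and Cd5l (0.0424), and leaving out the dimmest genes to Srxn1 (0.0450), Birc5 (0.0367), Per1 (0.0473) and Cd5l (0.0410). Calls also came without Control 1 (Rgs5, 0.0430), without Control 3 (Ccnd1, 0.0491; Birc5, 0.0259; Per1, 0.0333), without Control 4 (Srxn1, 0.00275; Gadd45b and Colec11, 0.0399 each; Psmb9, 0.0435; H2-Aa, 0.0280) and without LKB1 KO 2 (Cep55, 0.0297; Ect2, 0.0438; Gadd45b, 0.0227). Without both LKB1 KO 2 and Control 4, Srxn1 (0.00666), Gadd45b (0.00537), Cep55 (0.0316) and Birc5 (0.0412) passed.

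**Figure D1:**
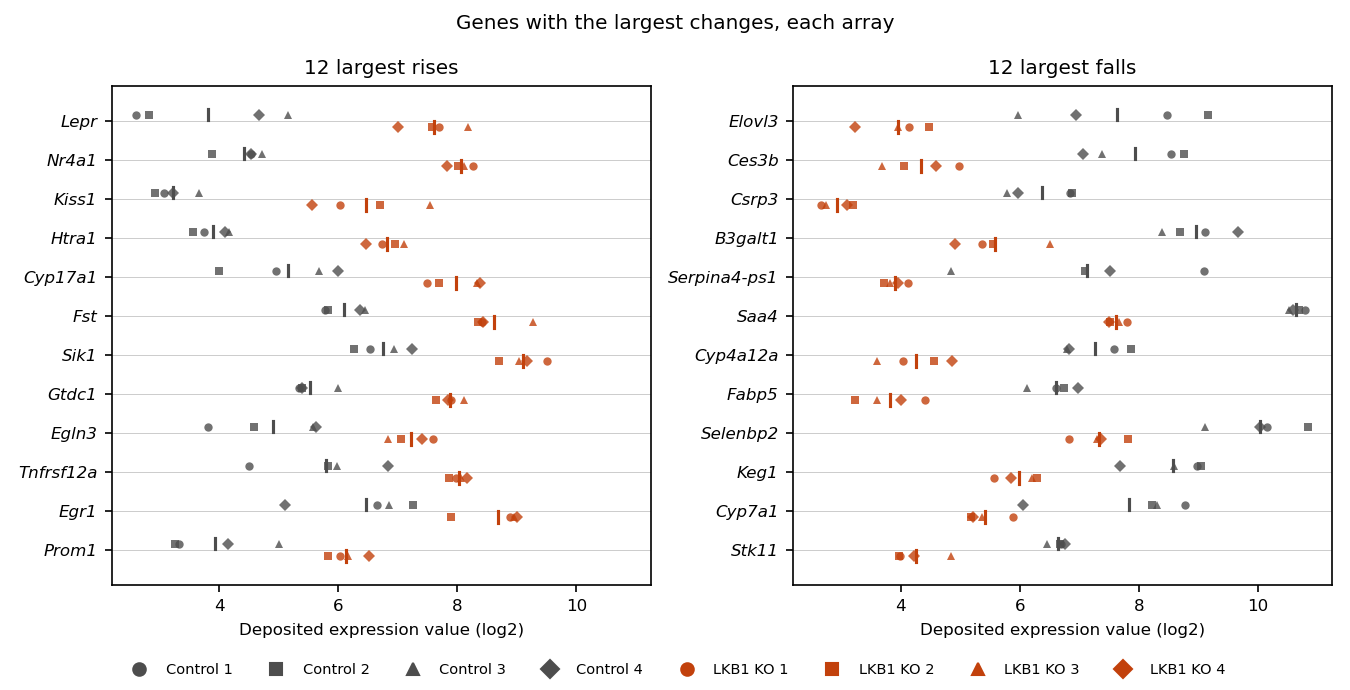
Deposited log2 values of the 12 genes with the largest rises and the 12 with the largest falls. Each symbol is 1 array, Control in grey and LKB1 KO in orange, and the vertical bars are group means (n = 4). The LKB1 KO arrays lie on one side of the Control arrays in every gene shown, as the rule for naming them required. The mean difference is 3.64 log2 units for Nr4a1 and -3.03 for Saa4.

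Genes of late cell division stood higher in the LKB1 KO livers than those of DNA replication. In the G2/M and mitosis list, 43 of 44 measured members had a higher mean in LKB1 KO, with a median difference of 1.11 log2 units. Over all genes, 3 of them rose and 0 fell: the mitotic kinase gene Plk1 (1.64, SE 0.36), the B-type cyclin gene Ccnb2 (1.54, SE 0.29) and the spindle checkpoint gene Mad2l1 (1.44, SE 0.30). Adjusted over the list alone, 33 rose and 0 fell. Camera called the list higher (adjusted p = 2.09e-22), but the adjusted p was 0.429 with an estimated correlation and the exact permutation p of the array medians was 0.0857, since the groups overlapped: Control arrays lay between -1.28 and 0.12 and LKB1 KO arrays between -0.15 and 1.03 around the mean of all arrays. The cytokinesis list (15 measured) had a median of 0.99, with 0 members past the threshold over all genes and 9 higher when adjusted over the list alone. Camera called it higher (adjusted p = 4.62e-07, and adjusted p = 0.429 with an estimated correlation), and its leading members were Cep55 (0.99, adjusted p = 0.0822) and Ect2 (1.87, adjusted p = 0.0939). Markers of endothelial cells and macrophages, described further on, stood lower in the same arrays, with medians of -0.34 and -0.39. The call of Plk1 ended without any array other than Control 3 or LKB1 KO 2 (adjusted p up to 0.135), that of Ccnb2 without Control 1, Control 4, LKB1 KO 1, LKB1 KO 3 or LKB1 KO 4 (up to 0.0845) and that of Mad2l1 without any array but Control 3 (up to 0.112).

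In the DNA replication and G1/S list, 0 of 36 members passed, over all genes or over the list alone. The cyclin gene Ccnd1 (0.75, adjusted p = 0.0909) and the thymidylate synthase gene Tyms (0.96, adjusted p = 0.136) came closest. The median was 0.17 (camera adjusted p = 0.0398, and adjusted p = 0.801 with an estimated correlation). It was -0.06 without Control 4 (adjusted p = 0.865), and the call was also lost without Control 1 (0.10, adjusted p = 0.322), LKB1 KO 3 (0.13, adjusted p = 0.385) or LKB1 KO 4 (0.08, adjusted p = 0.263). Without Control 2, Control 3 or LKB1 KO 2 it stood at 0.27, 0.41 and 0.32. The DNA damage repair list (20 measured) likewise had 0 members past the threshold in either count, with Atm at -0.60 and Fanci at 0.50. Its median of 0.20 (camera adjusted p = 0.0158, and adjusted p = 0.731 with an estimated correlation) lost its call without Control 1 (0.10), Control 4 (0.08), LKB1 KO 3 (0.19) or LKB1 KO 4 (0.18; adjusted p up to 0.334), and stood at 0.37 without Control 3 and 0.33 without LKB1 KO 2. Among 22 p53 targets, the stress kinase gene Plk3 (1.91), the antiproliferative gene Btg2 (1.47) and the mitotic gene Gtse1 (0.87) rose, while the death receptor gene Fas (-0.86) and the stress gene Sesn1 (-0.70) fell. Adjusted over the list alone, 8 rose and 2 fell. The p53 list had a median of 0.16 (camera adjusted p = 0.00249, fry adjusted p = 0.0139, and adjusted p = 0.152 with an estimated correlation), and 0.24 without Control 4. Gtse1, below the background gauge in 1 Control array, lost its call without any array other than Control 1 or Control 4 (adjusted p up to 0.106), and Sesn1 without any other than Control 3 or LKB1 KO 2 (up to 0.0985).

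**Figure D2:**
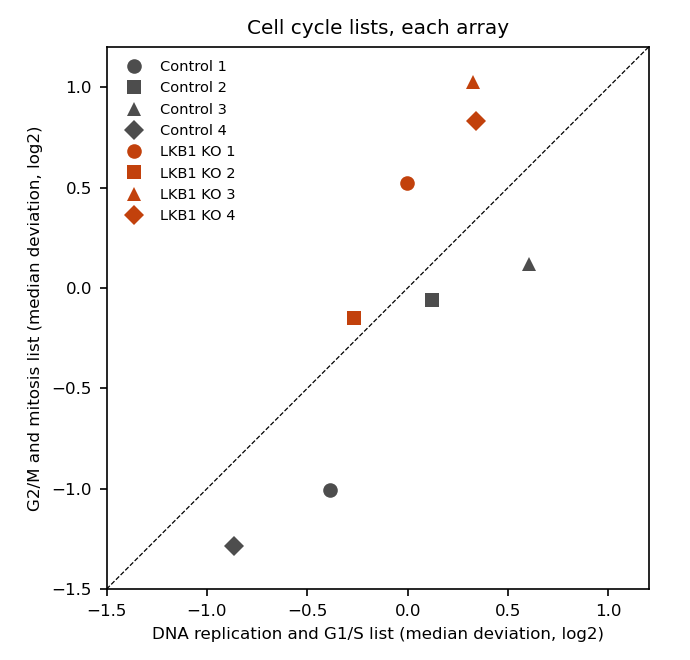
Median deviation of the G2/M and mitosis list (vertical axis, log2) against that of the DNA replication and G1/S list (horizontal axis, log2), each measured from the mean of all 8 arrays; each symbol is 1 array and the dashed line marks equal deviations. All 4 LKB1 KO arrays lie above the line, by 0.12 to 0.70 log2 units, and all 4 Control arrays lie below it.

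Immediate early genes, the transcription factor and feedback genes that respond first to a stimulus, were higher on balance in the LKB1 KO livers. Of 22 measured, 7 rose and 0 fell over all genes, 15 rose and 0 fell adjusted over the list alone, and 21 had a higher mean in LKB1 KO. Examples are Nr4a1 (3.64), Egr1 (2.22), Fos (1.49, adjusted p = 0.0270), Btg2 (1.47) and Atf3 (1.32, adjusted p = 0.00324). The median was 0.67 log2 units (camera adjusted p = 5.22e-16, fry adjusted p = 0.00156), the adjusted p was 0.0974 with an estimated correlation, and the arrays of the groups did not overlap (exact permutation p = 0.0286, the smallest possible). Fos lost its call without any array other than Control 3 or LKB1 KO 2 (adjusted p up to 0.0873) and Egr1 as given above. In the growth factor and EGFR list, 2 of 24 members rose, the phosphatase gene Dusp6 (1.75) and Igfbp1 (1.82), and 2 fell, the receptor genes Erbb3 (-1.5) and Egfr (-0.84). Adjusted over the list alone, 5 rose and 4 fell, the median was 0.06 (camera adjusted p = 0.485), and Igfbp1 lost its call without any array but Control 1 (adjusted p up to 0.143). None of 21 YAP/TEAD targets passed (median 0.04, camera adjusted p = 0.367), and 3 rose when adjusted over the list alone; Birc5 stood at 1.26 (adjusted p = 0.0512) and Gadd45b at 1.15 (adjusted p = 0.0830). None of 14 fetal liver genes passed in either count (camera adjusted p = 0.997), with Tff3 at 1.33 (adjusted p = 0.443) and Gpc3 at -0.31. The median of the fetal list was -0.02 and its mean 0.12.

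Bile acid genes held more falls than rises. Of 22 measured genes of bile acid synthesis and transport, 10 fell and 1 rose (11 and 4 adjusted over the list alone), with a median of -0.50. Falls were seen in Cyp7a1 (-2.43), the bile acid receptor gene Nr1h4 (-1.26, adjusted p = 0.00473), the organic anion transporter gene Slco1a1 (-1.18, adjusted p = 0.0102) and the synthesis enzyme gene Hsd3b7 (-1.10), and a rise in the basolateral efflux gene Slc51b (1.42). Slco1a1 and Cyp7b1 (-1.01), both among the falls, also stand on the male-biased list, so the falls of these lists are not fully separate. Camera called the list lower (adjusted p = 0.000282) and the array medians did not overlap (exact permutation p = 0.0286), but the adjusted p was 0.511 with an estimated correlation. Single arrays left out ended the calls of Cyp7a1 and Slc51b (any but Control 4, adjusted p up to 0.0998 and 0.118) and of Hsd3b7 (Control 2, LKB1 KO 3 or LKB1 KO 4, up to 0.0592). Cholesterol synthesis genes had lower means in 19 of 20 cases, with a median of -0.63 and 0 past the threshold over all genes or over the list alone. Cyp51 stood at -1.31 (adjusted p = 0.272) and Tm7sf2 at -0.53 (adjusted p = 0.300). Camera called that list lower (adjusted p = 4.09e-06), with an adjusted p = 0.511 under an estimated correlation and an exact permutation p of 0.143.

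Genes of glucose and fat metabolism moved in both directions. Among 19 genes of gluconeogenesis and glycogen, the coactivator gene Ppargc1a (1.34), the glucose-6-phosphatase gene G6pc (1.09) and Fbp1 (0.58) rose, while the glycogen targeting gene Ppp1r3c (-2.23) and the glucose-6-phosphate transporter gene Slc37a4 (-1.01) fell. Adjusted over the list alone, 3 rose and 5 fell, and the median was -0.02 (camera adjusted p = 0.705). Of 15 glycolysis genes, Pfkfb3 fell (-0.97) and Gckr stood at -0.58 (adjusted p = 0.108), with 2 rising and 2 falling over the list alone and a median of -0.08 (camera adjusted p = 0.553). Of 21 lipogenesis genes, the triglyceride synthesis genes Dgat2 (-1.19) and Gpam (-0.76) fell and 0 rose, and 1 rose and 4 fell adjusted over the list alone. The lipogenesis median was -0.14 (camera adjusted p = 0.0398, and adjusted p = 0.621 with an estimated correlation). Its call ended without Control 1, Control 2, LKB1 KO 2 (-0.05) or LKB1 KO 3 (adjusted p up to 0.347), with quantile normalization (adjusted p = 0.134), with median centring (0.0538), with array weights (0.124) and with the dimmest genes left out (0.117). It stood at -0.24, -0.31 and -0.29 without Control 3, Control 4 or LKB1 KO 4. Quantile normalization gave -0.09. Fatty acid oxidation and ketogenesis genes (25 measured) had 3 rises, in the acyl-CoA thioesterase genes Acot1 (2.08) and Acot2 (1.66) and the lipid droplet gene Plin2 (0.75), and 1 fall, in the nuclear receptor gene Ppara (-1.24). Adjusted over the list alone, 8 rose and 1 fell. Their median was 0.14 (camera adjusted p = 0.00134, and adjusted p = 0.511 with an estimated correlation), 0.08 without LKB1 KO 3 and 0.22 with array weights. Of 39 genes of amino acid catabolism and the urea cycle, the tryptophan-degrading enzyme genes Ido2 (-1.68) and Tdo2 (-1.16) fell and the aminotransferase gene Got1 rose (1.12), with 5 rising and 5 falling over the list alone (camera adjusted p = 0.952). The median of that list was 0.05, and its mean lay just below 0. Calls ended by single arrays were those of Ppp1r3c (LKB1 KO 4, adjusted p = 0.0507), Fbp1 (any but Control 3 or LKB1 KO 2, up to 0.135), Gpam (any but Control 3, up to 0.0893), Acot1 (any but Control 3 or Control 4, up to 0.0985) and Plin2 (any but Control 4 or LKB1 KO 2, up to 0.106).

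Some genes of each liver zone fell. In the pericentral list (22 measured), 6 fell and 1 rose (8 and 3 adjusted over the list alone): the cytochrome genes Cyp7a1, Cyp1a2 (-1.38) and Cyp2e1 (-1.09) and the nuclear receptor gene Nr1i3 (-1.05) were among the falls, and Lhpp was the rise (1.38). The median was -0.20 (camera adjusted p = 0.00309, and adjusted p = 0.511 with an estimated correlation), -0.12 without Control 2 and -0.34 without Control 4. In the periportal list (23 measured), 5 fell, among them Hsd17b6 (-1.59), the immunoglobulin receptor gene Pigr (-1.45), Cyp2f2 (-1.44) and Ctsc (-1.19), and 2 rose, Cyp17a1 and Fbp1. Adjusted over that list alone, 7 fell and 3 rose, and camera did not call it (median -0.05, adjusted p = 0.107). Of 20 xenobiotic receptor targets, Cyp2c55 rose (2.18) and Cyp1a2, Nr1i3 and Cyp3a13 (-1.02) fell, with 4 and 4 over the list alone and a median of -0.06 (camera adjusted p = 0.712). Of 20 NRF2 targets, the carboxylesterase gene Ces1g fell (-1.10) and the antioxidant gene Srxn1 stood at 1.83 (adjusted p = 0.0638), with 3 rising and 1 falling over the list alone. The NRF2 median was 0.13 (camera adjusted p = 0.0158, and adjusted p = 0.511 with an estimated correlation), 0.24 without dim genes, and its call ended without Control 4 (adjusted p = 0.0638) or LKB1 KO 4 (0.0698). Cyp2c55 lay below the background gauge in 2 Control arrays. Single arrays left out also ended the calls of Lhpp (any but Control 3, adjusted p up to 0.105), Hsd17b6 (any but Control 4, up to 0.128), Cyp2f2 (Control 1, Control 2, LKB1 KO 1 or LKB1 KO 2, up to 0.0810), Cyp2c55 (Control 1, Control 2, LKB1 KO 1, LKB1 KO 3 or LKB1 KO 4, up to 0.0636), Cyp3a13 (Control 1 or LKB1 KO 3, up to 0.0604) and Ces1g (any but Control 4, up to 0.0923).

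Male-biased liver genes were lower on balance in LKB1 KO. Of 15 measured, 8 fell and 0 rose, and 11 fell adjusted over the list alone. Next to Elovl3, Cyp4a12a and Selenbp2 these included the complement gene C6 (-1.77, adjusted p = 0.000947) and Cyp2d9 (-1.42, adjusted p = 0.00452). The median was -1.18 (camera adjusted p = 7.76e-14, fry adjusted p = 0.00490, and adjusted p = 0.152 with an estimated correlation), and the array medians did not overlap, at 0.19 to 0.96 in Control and -0.69 to -0.47 in LKB1 KO (exact permutation p = 0.0286). Among 17 female-biased genes, Cyp17a1 (2.83), Prom1 (2.21) and the transcription factor gene Cux2 (0.82) rose and 0 fell, with 4 rising and 1 falling over the list alone. Cux2 lay below the background gauge in 2 Control arrays and in the Control mean (3.72), so the size of its rise is uncertain. The median of the list was 0.19 (camera adjusted p = 0.00864, and adjusted p = 0.323 with an estimated correlation), and lay between 0.16 and 0.41 with single arrays left out (0.30 without Control 1, 0.41 without Control 3, 0.30 without LKB1 KO 4). Without dim genes it was 0.82. Without LKB1 KO 3 the list was not called (adjusted p = 0.0610), and Cux2 lost its call without Control 1 or LKB1 KO 3 (adjusted p up to 0.0605). The 4 measured genes of the list of Y-linked genes and Xist included Uty at -0.39 and Kdm5d at -0.41, with 0 past the threshold in either count and a median of -0.28 (camera adjusted p = 0.0758). Without Control 4 that list was called lower (-0.41, adjusted p = 0.0126).

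Genes of the acute phase list had lower means in LKB1 KO. The list holds genes of plasma proteins of the inflammatory response and also others, such as Socs3, Stat3 and Steap4. All 29 measured members had a lower mean, 8 fell over all genes and 13 adjusted over the list alone, and 0 rose. Beside Saa4 these were led by Orm3 (-1.93), Apcs (-1.51), Orm2 (-1.25) and Steap4 (-1.06). The median was -0.31 (camera adjusted p = 2.32e-18, fry adjusted p = 0.00161, and adjusted p = 0.152 with an estimated correlation; exact permutation p = 0.0286). Hepatocyte markers, described further on, moved the same way in these arrays (median -0.20), as they did beside the bile acid, zonation and male-biased lists. Orm3 and Cyp2f2 lost their calls without the same 4 arrays (Orm3 up to adjusted p = 0.0597), Orm2 without Control 1, Control 2, Control 4 or LKB1 KO 2 (up to 0.0846) and Steap4 without Control 1, Control 2 or LKB1 KO 1 (up to 0.0597). The interferon list (28 measured) had 0 members past the threshold, 1 rise and 1 fall over the list alone, a median of -0.01 and a mean of 0.01 (camera adjusted p = 0.494), with Psmb9 at -0.89 (adjusted p = 0.0850) and Cxcl10 at 1.77 (adjusted p = 0.0929). Of 27 genes of the unfolded protein and integrated stress response, Atf3 (1.32), the lipoprotein receptor gene Vldlr (1.30) and the serine synthesis gene Psat1 (0.82) rose, and over the list alone 3 rose and 5 fell, with a median of -0.05 (camera adjusted p = 0.459). Psat1 lay below the background gauge in all 4 Control arrays, so the size of its rise is uncertain. Vldlr lost its call without Control 1, Control 2, LKB1 KO 1, LKB1 KO 3 or LKB1 KO 4 (adjusted p up to 0.0705) and Psat1 without any array other than Control 4 or LKB1 KO 3 (up to 0.109). Among 18 clock genes the repressor gene Nr1d1 fell (-1.77, adjusted p = 0.00472) and Per1 stood at 1.05 (adjusted p = 0.0643), with 5 rising and 1 falling over the list alone. The clock median of 0.11 was not called (camera adjusted p = 0.485), except without Control 3 (0.27, adjusted p = 0.0352).

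Marker lists of hepatocytes, endothelial cells and macrophages had lower medians in the LKB1 KO samples. Of 21 hepatocyte markers, Tdo2 (-1.16), the transcription factor gene Cebpa (-0.99) and Kng1 (-0.72) fell and 0 rose, and 8 fell over the list alone (median -0.20, camera adjusted p = 4.62e-07, fry adjusted p = 0.00156, and adjusted p = 0.154 with an estimated correlation). Of 23 endothelial markers, the sinusoidal genes Clec4g (-0.83), Fcgr2b (-0.77) and Gpr182 (-0.68) and the VEGF receptor gene Kdr (-0.72) fell and 0 rose, with 10 falling over the list alone (median -0.34, camera adjusted p = 9.21e-08, fry adjusted p = 0.00994, and adjusted p = 0.152 with an estimated correlation). Array medians of both lists did not overlap between the groups (exact permutation p = 0.0286 for each). Among 21 Kupffer cell and macrophage markers, the receptor gene Csf1r fell (-0.78), Cd5l stood at -0.77 (adjusted p = 0.0549) and 5 fell over the list alone (median -0.39, camera adjusted p = 4.06e-07, and adjusted p = 0.432 with an estimated correlation). Of 20 neutrophil markers the protease gene Prtn3 fell (-2.02), also the single fall over the list alone, and S100a8 stood at -1.07 (median -0.29, camera adjusted p = 0.0202, and adjusted p = 0.619 with an estimated correlation). The protease gene Elane, on the same list, did not differ and lay below the background gauge in both groups (3.41 in Control, 3.40 in LKB1 KO). Prtn3 is also among the called genes near Stk11, described at the end. The 24 stellate cell and fibroblast markers had 0 past the threshold and 5 lower over the list alone, with Rgs5 at -1.02 and Colec11 at -0.69 (median -0.23, camera adjusted p = 0.0176, and adjusted p = 0.657 with an estimated correlation). The neutrophil call ended without Control 1, Control 4 (-0.13) or LKB1 KO 3 (adjusted p up to 0.169) and the stellate call without Control 4 (-0.08), LKB1 KO 2 (-0.12) or LKB1 KO 4 (-0.14; adjusted p up to 0.334). Array weights ended both calls (adjusted p = 0.0520 for neutrophil markers, and 0.116 with a median of -0.07 for stellate markers), and leaving out the dimmest genes ended the stellate call (0.0596). Single arrays left out ended the calls of Kng1 (Control 2, Control 3, Control 4, LKB1 KO 3 or LKB1 KO 4, adjusted p up to 0.0697), Fcgr2b and Kdr (any but Control 4, up to 0.108 and 0.130), Gpr182 (Control 2, LKB1 KO 1 or LKB1 KO 3, up to 0.0634) and Csf1r (any but Control 2, up to 0.110).

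The other cell type lists were not called, apart from the pancreatic one. Cholangiocyte and progenitor markers (14 measured) held the rise of Prom1, also over the list alone, with Krt23 at 0.85, a median of -0.03 and a mean of 0.17 (camera adjusted p = 0.568). Erythroid markers (10 measured) held a fall of the heme synthesis gene Alas2 (-1.03), also over the list alone, with Car1 at -0.71, a median of 0.02 and a mean of -0.20 (camera adjusted p = 0.441). Alas2 lost its call without any array but Control 4 (adjusted p up to 0.141). None of 22 T and NK cell markers (median 0.10, camera adjusted p = 0.320; Cd8a 0.44, Klrd1 -0.41), 15 B and plasma cell markers (0.10, 0.318; Ebf1 0.25, Ighm 0.52), 16 dendritic cell markers (0.03, with a mean of -0.09, 0.712; H2-Aa -1.26, Ccr9 0.32) or 11 mast cell and platelet markers (0.10, 0.419; Kit -0.32, Gp1bb 0.22) passed in either count. The 12 pancreatic acinar markers had 0 past the threshold in either count, with Ctrb1 at 1.25 and Cel at 0.42 (median 0.29, camera adjusted p = 0.0398, and adjusted p = 0.724 with an estimated correlation). Without LKB1 KO 4, whose list median stood 0.97 above the mean of all arrays, the pancreatic median was 0.04 (adjusted p = 0.681), and it was not called without Control 2, Control 3 or Control 4 either (adjusted p up to 0.114 for Control 3). It stood at 0.47 without LKB1 KO 1 and 0.46 without LKB1 KO 3, and its call ended with quantile normalization (adjusted p = 0.0868) and with the dimmest genes (0.0818) or its dimmest members (0.0688) left out.

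Over the 40 lists, camera with its preset correlation called 10 higher and 11 lower. With an estimated correlation it called 0, the smallest adjusted p being 0.0974 for the immediate early genes. Fry called 6, all among the 21: the p53 and immediate early lists higher, and the acute phase, male-biased, hepatocyte and endothelial lists lower. By exact permutation 9 lists reached the smallest p of 0.0286, where chance gives 1.14 of 40, and 0 passed after adjustment (0.127).

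**Figure D3:**
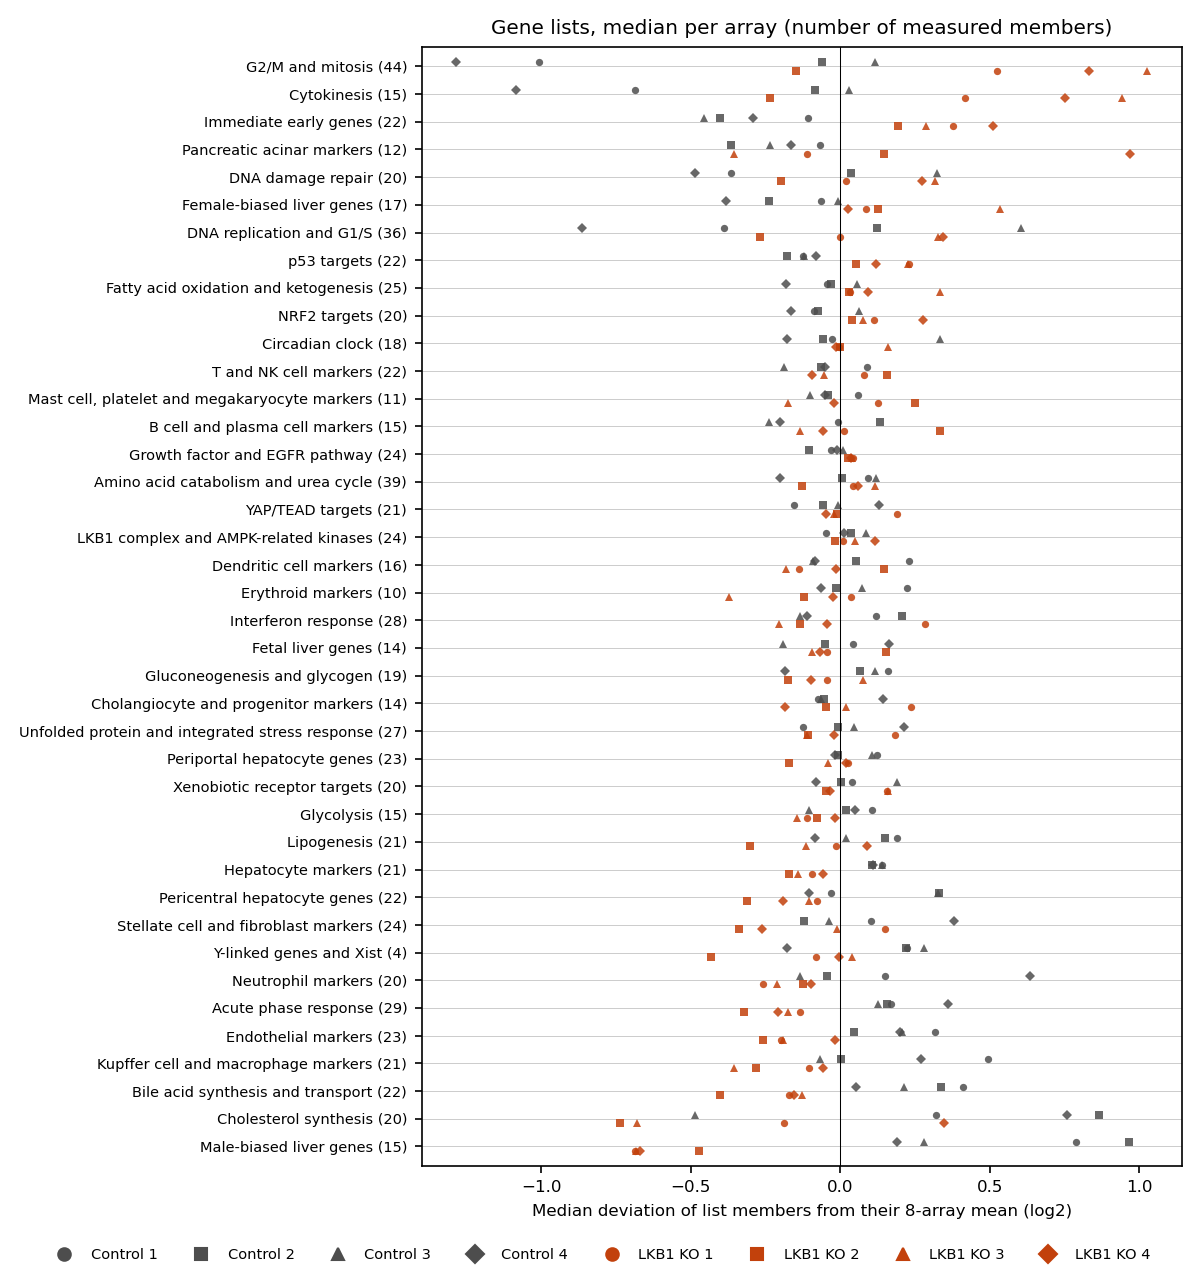
Median deviation of the members of each of the 40 lists from their mean over all 8 arrays (log2, horizontal axis); each symbol is 1 array, Control in grey and LKB1 KO in orange, and brackets give the number of measured members. The lists are ordered by median difference, from 1.11 for the G2/M and mitosis list at the top to -1.18 for the male-biased liver genes at the bottom.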

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

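In 324 sets of 4 arrays, from the named genes and the list medians, 21 arrays stood apart from the other 3 of their group by Dixon's test, where chance gives 16.2. LKB1 KO 2 accounts for 7 of them and Control 4 for 5.

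Within the LKB1 KO group, the follistatin gene Fst stood at 9.27 in LKB1 KO 3 (8.34 to 8.43 in the others). Egr1 stood at 7.90 in LKB1 KO 2 (8.89 to 9.0), and Pfkfb3 at 4.67 in LKB1 KO 1 (5.07 to 5.13). Gckr was at 7.29 in LKB1 KO 2 (7.83 to 7.92), where the lipoprotein receptor gene Vldlr was at 5.43 (5.84 to 5.91) and the pericyte gene Rgs5 at 3.84 (4.69 to 4.80). The immunoglobulin gene Ighm reached 7.05 in the same array, against 5.15 to 5.30 in the other LKB1 KO arrays. Psat1 stood at 3.83 in LKB1 KO 3 (4.29 to 4.36), the macrophage gene Cd5l at 6.71 in LKB1 KO 4 (6.27 in each of the others) and Steap4 at 8.67 in LKB1 KO 4 (9.30 to 9.40).

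Within the Control group, Gtdc1 stood at 5.99 in Control 3 (5.34 to 5.39) and Acot2 at 3.90 in Control 1 (4.43 to 4.51). Control 4 held Slco1a1 at 9.86 (10.51 to 10.63), Steap4 at 10.65 (10.06 to 10.13) and Colec11 at 5.47 (6.04 to 6.08).

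Among the list medians, bile acid genes in LKB1 KO 2 stood at -0.40 (-0.17 to -0.13 in the other LKB1 KO arrays) and male-biased genes in that array at -0.47 (-0.69 to -0.67). YAP/TEAD targets stood at 0.19 in LKB1 KO 1 (-0.05 to -0.01) and clock genes at 0.16 in LKB1 KO 3 (others at 0 or just below). In Control 4 the list of Y-linked genes and Xist stood at -0.18 (0.22 to 0.28 in the other Control arrays) and the cholangiocyte list at 0.14 (-0.08 to -0.05).

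Outside the named genes, 29 of the 2021 rows without a gene symbol passed the threshold when all rows were fitted, 7 higher and 22 lower in LKB1 KO.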

How the results depend on the processing

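Of the settings below, the fit without both LKB1 KO 2 and Control 4 was chosen after the arrays had been seen. Stk11 kept its direction and its call under every alternative run, between -2.59 and -2.30 with single arrays left out. With single arrays left out, between 213 and 491 genes passed, 42 to 144 higher and 164 to 382 lower; fewer samples lower the power of each such fit. Without moderation of variances 97 genes passed (13 higher, 84 lower), at an adjusted p under 0.01 139 (24 and 115), and with array weights 721, of which 254 were higher. Quantile normalization called 198 higher. With the replicate number as a block 268 passed (186 lower), 243 of them among the 458, and 20 lists. The counts stayed within 1.5 times the 458, 113 and 345 reported under median centring (408), the dimmest genes left out (586), a trended and robust prior (576), all rows (482), a fold of at least 1.5 (452) and the fit without LKB1 KO 2 and Control 4 (459, of which 305 are among the 458). The titles do not state that replicate numbers pair the samples, and same-numbered arrays showed no clear common deviation (correlations of -0.04, -0.11, 0.18 and -0.02; replicate 3 alone correlated best with its own number), which does not exclude a shared day or litter. Of 86 named genes past the threshold other than Stk11, 50 kept their calls in all 8 fits with an array left out, and 36 lost them in at least 1, as given with the results, while 66 lost them without moderation of variances, 24 without both LKB1 KO 2 and Control 4 and 17 with the block; 0 turned direction. Of the 21 list calls, 13 held in all 8 fits, the estimated correlation left 0 and fry 6. The DNA replication list lay between -0.058 and 0.41 with single arrays left out; the reversal, uncalled, came without Control 4, and the cause was not tested. Without both LKB1 KO 2 and Control 4, 17 lists were called, and the lists that lost their calls were DNA replication (0.09), lipogenesis (-0.21), neutrophil (-0.21), stellate (0.01) and pancreatic (0.31), while the list of Y-linked genes and Xist gained one (-0.28, adjusted p = 0.0262). The block ended the lipogenesis call (adjusted p = 0.0627) and gave calls to Srxn1 (0.0358) and Per1 (0.0411). Why the other counts moved was not tested either. The mean over several rows per gene could not be run as a separate setting. Signal over background limits the dim genes: mean levels ran from 2.11 at the 10th percentile to 7.21 at the 90th.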

Other observations

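The tests in this part were chosen after the results had been seen, except the counts over other splits of the arrays. A shift is the median of all differences between an LKB1 KO array and a Control array. Its 97.1% exact interval runs from the smallest to the largest of these differences.

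Cytochrome P450 genes held more falls than their number among all genes would give. When genes were put in 3 equal bins by mean level and the dimmest bin was left out, 18 of 73 Cyp genes fell and 2 rose, so 24.7% fell against 2.22% of the 15456 genes kept (Fisher's exact test, odds ratio 15.2, 95% confidence interval 8.28 to 26.6, adjusted p = 2.54e-12 over 64 families formed from symbol prefixes, in both directions). Beside those already described, falls included Cyp2d40 (-1.91), Cyp2c67 (-1.5), Cyp2d13 (-1.35) and Cyp2c23 (-1.33). These genes were named after their values were seen. Within the brightest bin 17 of 46 Cyp genes fell (37.0%, against 3.89%), and both scalings tried, quantile normalization and median centring, again gave 18 falls and 2 rises. Hepatocyte markers stood lower in the same arrays (median -0.20, exact permutation p = 0.0286). Probes shared between close paralogs were not examined, so it is not known whether the 18 are independent.

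Falls were also over-represented among solute carriers, with 21 falls and 4 rises among 272 Slc genes, of which the others did not pass (7.72%, odds ratio 3.86, 95% confidence interval 2.32 to 6.13, adjusted p = 4.88e-05 by Fisher's exact test). The organic anion transporter gene Slc22a7 (-2.39), the citrate and dicarboxylate transporter genes Slc13a3 (-1.86) and Slc13a5 (-1.83) and the lysosomal gene Slc46a3 (-1.46) were among the falls. Slc13a5 had a mean of 3.66 in LKB1 KO, below the background gauge of 3.73, so the size of its fall is uncertain. Hepatocyte markers stood lower in the same arrays here too. The rises were in Slc51b and the mitochondrial carrier genes Slc25a30 (1.33), Slc25a22 (1.21) and Slc25a15 (0.76). Under quantile normalization 19 fell and 8 rose, and under median centring 18 fell and 1 rose.

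The 8 arrays can be split into 4 and 4 in 35 ways. The real split gave 458 genes past the threshold and the highest other gave 1. With 1 of 35 splits as large, the smallest share possible, the gene count argues against chance but does not exclude it. The other splits mix the groups, so a real group difference widens their spread and lowers their counts. The splits cannot tell the genotype from anything else that a group shared. For the 21 list calls of camera with its preset correlation chance is not excluded either. Another split, Control 1, Control 2, Control 4 and LKB1 KO 1 against the rest, also called 21 lists (2 of 35 as large), with 0 genes past the threshold. That split keeps most arrays of each group together, so it still carries part of the group difference. Splits with as many Control as LKB1 KO arrays on each side called up to 15 lists, also with 0 genes past the threshold.

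The first pattern is the G2/M list standing higher relative to the G1/S list, with a difference per array of -0.43 ± 0.18 in Control and 0.46 ± 0.24 in LKB1 KO (SD, n = 4; shift 0.93, 97.1% exact interval 0.31 to 1.32; exact two-sided permutation p = 0.0286, the smallest possible). Genes of the same mean level (3124) had a median difference of -0.057, which argues against a bias with brightness, and of 6 marker lists of other cell types 0 were called higher and 3 lower (highest median 0.10; 2 of their 121 genes stand on another list), which argues against more of all these cells together. Those 3 calls were lost with an estimated correlation (adjusted p = 0.152 for endothelial, 0.432 for macrophage and 0.657 for stellate markers, the last also without Control 4, LKB1 KO 2 or LKB1 KO 4), so the argument rests on the endothelial list, lower in all 4 LKB1 KO arrays than in any Control array (exact permutation p = 0.0286). Of their abundant genes, those of endothelial cells, macrophages and stellate cells had lower means. Among these, the endothelial gene Clec4g passed the test (-0.83, mean level 8.23). The other endothelial gene, Dpp4, hardly differed and did not pass (-0.07, mean level 7.98). Nor did C1qb (-0.48, 7.51) and Vsig4 (-0.35) of macrophages, or Dcn (-0.43, 8.53) and Sparc (-0.44) of stellate cells. Those of dendritic cells were also lower, without passing the test (Cd74 -0.43, H2-Ab1 -0.15). Those of T, NK and B cells had higher means without passing the test (Klrb1c 0.17, Ccl5 0.40, Ly6d 0.73, Igkc 0.16), so more lymphocytes alone are not excluded. Ly6d (SE 0.77) also stands on the fetal liver list. The test of the G2/M minus G1/S difference restates the pattern and supports no explanation over another, so a different position in the cell cycle at 48 h stays open, with a single time point and no other measure of the cycle to test it.

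The second pattern is the lower level of the male-biased list. Animals of different sex are argued against by the Y-linked genes (shift -0.33, exact interval -0.88 to 0.36) and Xist (-0.59 to 0.09), which stayed far from the change of over 2 log2 units set as the bound. Their levels argue the same way. Xist lay between 2.42 and 3.01 in every array, below the background gauge of 3.73. Above it in both groups were the means of Eif2s3y (7.27 in Control, 7.13 in LKB1 KO), Uty (6.05 and 5.66) and Kdm5d (5.31 and 4.90). Both groups thus had the levels of male samples. The male-biased list stood further below Control than the hepatocyte markers (shift of the difference -0.85, exact interval -1.47 to -0.38). Both medians had been seen, and the male-biased one was the lowest of the 40 lists, so this difference largely restates the pattern. It shows that the falls were unequal, and cannot decide whether a general fall of hepatocyte transcripts is part of the cause. A weaker growth hormone and STAT5 signal stays open. The mean of the feedback genes Socs2 (0.35) and Cish (0.29) differed by 0.32 between the group means. Its shift was 0.12, with an exact interval of -0.27 to 1.49.

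The last pattern is the higher level of immediate early genes. Rougher or slower handling of the LKB1 KO samples stays open: their shift exceeded that of 10 heat shock genes by 0.44, but the exact interval of -0.48 to 1.33 includes 0. A stronger CREB and CRTC signal stays open too. Its 11 targets outside the immediate early list shifted by 0.66 (exact interval 0.36 to 0.96), higher in all 4 LKB1 KO arrays than in any Control array. Of them 4 rose (Sik1, Ppargc1a, Irs2 at 1.33 and G6pc), while Pck1 (-0.02) and Tat (0.17) did not pass the test. Targets such as Nr4a3, Sik1, Per1 and Crem can themselves respond early to a stimulus. The shift therefore cannot separate this signal from a general early response, whatever its cause. The calls of Sik1, Ppargc1a and G6pc had been seen before these targets were chosen. The 5 targets on no fixed list (Irs2, Crem, Pde4d, Pde4b and Nr4a3) all had higher means, with a shift of 0.39 (exact interval 0.21 to 0.78) and 1 call. That call was Irs2, and the limma adjusted p of the others ran from 0.174 (Crem) to 0.568 (Pde4b). Nr4a3 lay below the background gauge in both group means (3.17 in Control, 3.64 in LKB1 KO). Pde4b did so in the Control mean (3.64), so the sizes of these rises are uncertain.

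Genes next to Stk11 were examined for linked DNA around the targeted allele. Of the nearest 50 measured genes, 25 on each side, 3 were past the threshold (6%, against 1.96% of the other genes; odds ratio 3.19, interval 0.63 to 9.96, Fisher's exact p = 0.0756): Prtn3, Cbarp (0.76) and Gamt (-0.77). With 10 genes on each side 2 of 20 were (10%, odds ratio 5.54, exact p = 0.0583), and with 50 on each side 3 of 100 (3%, odds ratio 1.54, exact p = 0.451). The intervals are too wide to tell linked DNA from none.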
